A study of Homo sapiens with 12 samples.

How the data were processed

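The samples were untreated BxPC3, Panc327 and SUIT2 cells, grown under standard conditions, with 2 H3K27ac ChIP libraries and 2 input libraries per line, per the labels. Chromatin was crosslinked with paraformaldehyde and sonicated, and libraries were made with a KAPA HyperPrep kit, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie 1.1.1 and MACS2 were used with the hg19 build; the MACS2 version and settings were not given in the sources used here.

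Each of the 6 H3K27ac libraries had its own deposited peak list in narrowPeak form, so peaks had been called per library and not on pooled libraries. The deposited score column and the peak summit column were not used. The deposited fold of each peak is the authors' ratio of ChIP pile-up to local background, and it was used only to describe peaks within a list and to recover the pile-up. The deposited −log10 p-value and −log10 q-value of each peak are the authors' values from the peak caller, used to filter and rank peaks within a list. Every peak had a −log10 p of at least 10.0 and a −log10 q above 8.11. No 2 lists were identical. Chromosomes 1 to 22 and X were used, which left out at most 3 peaks of a list.

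Peak sets were compared by overlap. Covered bases were compared with the Jaccard index. Peaks of all 6 lists that shared at least 1 bp were merged into regions, and bedtools 2.31.1 gave the same 58994 regions. A region was marked in a line when both libraries had a peak in it and unmarked when neither had. Regions of a line alone were marked in it with no peak in the other 4 libraries, and regions missing from a line were marked in both others with no peak in it. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

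The deposited values also held the depth behind the peaks. MACS2 is known to give the fold as pile-up over local background, each with a pseudocount of 1, and the p as a Poisson tail. Solving both for a whole number of reads explained 99.9 to 100% of the peaks of each list within 0.001 of the −log10 p. It gave each peak's pile-up and its local background, which comes from the input library. Estimated tag numbers further assume the MACS2 default human genome size of 2700000000 bp and a fragment length equal to the narrowest peak of each list. For the BxPC3 ChIP libraries they also use a fitted scale of the pile-up, 0.752 and 0.652 in replicates 1 and 2. Estimated tag numbers were 20600000 and 28100000 for the BxPC3 inputs, 27800000 and 29100000 for Panc327 and 51400000 and 59700000 for SUIT2. They are estimates that rest on these settings, which no label states. Background was summarised as the median ratio to the genome-wide background in 2 Mb windows with at least 8 peaks in both libraries of a line. The background cannot fall under the genome-wide level, so losses of DNA are not visible in it.

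The design fixed before the data were examined compared libraries and lines by overlap, with all 15 ways of splitting the libraries into pairs as the exact permutation test. It also planned promoter counts and tests of 34 gene lists (pancreatic tumour subtypes, ductal, acinar, endocrine, fibroblast, haematopoietic, endothelial, neuronal and liver markers, stress response, sirtuin and signalling genes among them). These need gene positions on hg19. The only gene table at hand is on the GRCh38.p14 assembly; coordinates were not converted, and no value reported here uses its positions, so no gene list and no promoter result is given. The same limit kept regions near transcript starts in the stitched clusters. The rule for named genes was written with this case in mind: regions are named by position, per line the 10 line-only regions with the most covered bases, of which the broadest are given. Other positions in the text are the top entries of ranked tables and were chosen after their values were seen.

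The chromosome test, the 1 Mb and 2 Mb windows, the threshold of 2 times the background, the −log10 q of at least 20 and the gaps of at least 20 regions were chosen after the data were seen. In the chromosome test, regions marked in at least 1 line were cut into blocks of 25 neighbours, which were shuffled over the genome 10000 times. The replicate number was no sign of pairing: libraries of different lines with the same number had a mean Jaccard index of 0.370 and those with different numbers 0.368. A relation across chromosomes was at first set against gene density from the GRCh38.p14 table; that version was dropped because that assembly is not the one of the peaks, and the density of H3K27ac regions in the other lines took its place after the result of the first version had been seen.

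On simulated data, all 7 region classes were recovered over 58994 regions. Over 20 simulated runs the block test called a chromosome enriched 1.3 times in 15 and one enriched 1.5 or 2 times in all 20. It called an unchanged one in 0, and made 0 to 4 calls on the other chromosomes over the 20 runs. The simulated chromosomes were of nearly equal size, with a higher label rate than the real classes and adjustment over the chromosomes of a run alone. These rates of calls may therefore not hold for the real classes. Pile-up and background were recovered for 100% of 2996 and 2972 simulated peaks. The alternatives tried were a stricter q, equal numbers of peaks per list, a wider merging distance, a larger required overlap, another overlap measure, the replicate number as a block, shorter stretches, a shorter joining distance and leaving out each library.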

Results

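H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was profiled by ChIP-seq in 3 human pancreatic ductal adenocarcinoma cell lines, BxPC3, Panc327 and SUIT2. All cells were untreated. BxPC3 is an established epithelial line from a primary pancreatic tumour, and SUIT2 is an established line from a liver metastasis of a pancreatic tumour. Each line gave 2 H3K27ac libraries and 2 input libraries, so the series held 12 samples. A list of called peaks was used for each of the 6 H3K27ac libraries, and the 6 input libraries entered only through the background that the peak caller took from them. The series title names SIRT6, a chromatin-bound deacetylase, and the integrated stress response, the programme that lowers translation under stress. The peak lists describe the untreated H3K27ac landscape in which that study worked, and no treated or SIRT6-depleted cells were compared here.

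The peak lists held 34113 and 38335 peaks in BxPC3 replicates 1 and 2, 27776 and 29139 in Panc327, and 29983 and 31421 in SUIT2, on chromosomes 1 to 22 and X. Mean peak numbers were 36224 ± 2985 in BxPC3, 28458 ± 964 in Panc327 and 30702 ± 1017 in SUIT2 (SD, n = 2). Depth was not stated in the lists. It was estimated from the fold and −log10 p of the peaks, assuming the usual settings of the peak caller, at 27400000 and 43100000 ChIP tags in BxPC3, 13800000 and 24400000 in Panc327, and 36700000 and 42400000 in SUIT2. Panc327 replicate 1 therefore had the fewest estimated tags of the 6 libraries, and the BxPC3 pair differed most in absolute terms. At the fitted scale of the BxPC3 pile-ups, which brings that pair to 20600000 and 28100000 tags, the Panc327 pair differed most.

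The breadth of called H3K27ac differed between the libraries. SUIT2 peaks covered 60.1 and 63.3 Mb, against 48.7 and 54.6 Mb in BxPC3 and 34.1 and 46.3 Mb in Panc327. The median SUIT2 peak was 1504 and 1481 bp wide in replicates 1 and 2, the median BxPC3 peak 1070 and 1030 bp, and the median Panc327 peak 1008 and 1292 bp. SUIT2 held 301 and 332 peaks of at least 10 kb, BxPC3 59 and 82, and Panc327 9 and 32. Covered length averaged 61.7 ± 2.25 Mb in SUIT2, 51.7 ± 4.15 Mb in BxPC3 and 40.2 ± 8.65 Mb in Panc327 (SD, n = 2). Both SUIT2 libraries lay above all 4 others in covered length, median width and number of wide peaks. Covered length also rose with the estimated ChIP tags in every library except BxPC3 replicate 2, which had the most tags. The BxPC3 pile-ups had fitted scales of 0.752 and 0.652, which bring them to the estimated input tags of 20600000 and 28100000. At those numbers BxPC3 replicate 2 was no exception. Only BxPC3 replicate 1 then covered more than a library with more tags, Panc327 replicate 2. Depth and line were therefore not separated for covered length. With 2 libraries against 2, the smallest exact permutation p is 0.333, so no test between lines was made. The labels do not say whether replicates came from separate cultures, so every spread and p given here measures only the spread between these libraries.

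Of the bases of the 5 widest SUIT2 peaks in each library, the other SUIT2 library also called 96.7 to 100%, but not always as 1 peak. The widest of all, on chromosome 11 from 65144009 to 65215092 (hg19, as are all positions) in replicate 2, was 71.1 kb wide and was called as 5 peaks in replicate 1, the widest of them 38.9 kb. The peak on chromosome 9 from 38022839 to 38071111 in replicate 2 (48.3 kb) was likewise called as 3 peaks in replicate 1. Others were matched by a peak of similar width: on chromosome 7 a peak covered 130550866 to 130612984 in SUIT2 replicate 1, a width of 62.1 kb, and 130551059 to 130612386 in replicate 2, a width of 61.3 kb. On chromosome 20 a SUIT2 peak ran from 48282372 to 48331847 in replicate 1 and from 48282894 to 48332118 in replicate 2. On chromosome 17 the SUIT2 peak from 57899367 to 57942309 in replicate 1 matched one from 57899327 to 57943436 in replicate 2. The widest BxPC3 peak lay on chromosome 22 in both libraries, at 46459855 to 46485039 in replicate 1 and 46459961 to 46484455 in replicate 2, with widths of 25.2 and 24.5 kb. In Panc327 the widest peaks of the libraries were different: chromosome 7, 5458001 to 5470730, in replicate 1 (12.7 kb) and chromosome 12, 28116880 to 28138368, in replicate 2 (21.5 kb). The peak on chromosome 12 lay between 26 and 30 Mb, where the Panc327 input background was raised. A Panc327 domain on chromosome 6 was among the 5 widest of both libraries, at 10409837 to 10421927 in replicate 1 and 10406322 to 10421982 in replicate 2. No annotation of hg19 was used here, so peaks and regions are named by position alone.

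On average, libraries of the same cell line shared more of their H3K27ac landscape than libraries of different lines, by far in SUIT2 and BxPC3 and by less in Panc327. The Jaccard index, the length covered in both lists over the length covered in either, was 0.868 for the SUIT2 pair, 0.814 for the BxPC3 pair and 0.519 for the Panc327 pair. Libraries of different lines had a mean index of 0.369. Panc327 and SUIT2 were the least alike, with a mean of 0.312 over 4 pairs, while BxPC3 reached 0.404 with Panc327 and 0.392 with SUIT2. The mean within lines exceeded the mean between lines by 0.364, the largest value among the 15 ways of splitting 6 libraries into pairs (exact permutation test, one-sided p = 0.0667). This p is the smallest those splits can give. The highest of the other splits gave 0.147.

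**Figure D1:**
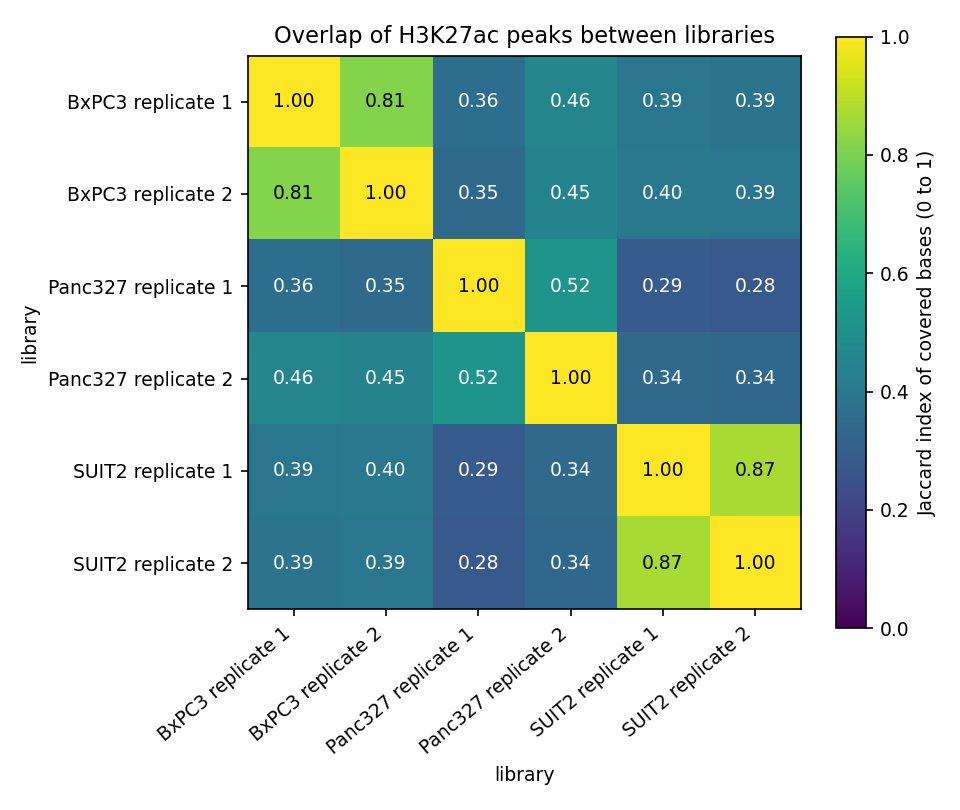
Jaccard index of the bases covered by called H3K27ac peaks (color, 0 to 1) for each pair of the 6 libraries, listed on both axes. The SUIT2 pair reached 0.868 and the BxPC3 pair 0.814, while the Panc327 pair (0.519) lay closer to the pairs of different lines.

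The Panc327 libraries differed from each other in what they shared with the other lines. Panc327 replicate 2 had an index of 0.456 and 0.449 with the BxPC3 libraries, and Panc327 replicate 1 had 0.362 and 0.346. Both BxPC3 libraries and no SUIT2 library held 1695 regions that were called in Panc327 replicate 2 alone of its line, and 348 called in replicate 1 alone. For regions held by both SUIT2 libraries and no BxPC3 library the counts were 342 and 362. Regions held by all 4 of those libraries were also called more often in replicate 2 alone, 1143 against 474. With the same number of peaks from each list, the BxPC3-held counts were 1224 and 287 and those held by all 4 were 871 and 441. At a −log10 q of at least 20, chosen after the data were seen, the BxPC3-held counts were 1000 and 374, the SUIT2-held counts 229 and 399, and those held by all 4 were 739 and 615.

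Merging the 6 lists gave 58994 regions, of which 43240 were marked, meaning called in both libraries of at least 1 line. A core of 12721 regions carried a peak in all 6 libraries, 29.4% of the marked regions, with a median width of 2780 bp. These shared regions held the strongest signal of every line: of the 1000 peaks with the highest −log10 q in each list, between 951 (Panc327 replicate 2) and 981 (Panc327 replicate 1) fell in them. Only 3 to 11 of those peaks per list fell in regions of that line alone. A shared region needs a called peak in all 6 lists, which by construction favours strong peaks. Line-only regions had median widths of 814 bp in BxPC3, 1145 bp in Panc327 and 1150 bp in SUIT2; a shared region merges peaks of 6 lists and a line-only region those of 2, so shared regions are wider by construction. The shared count fell to 5255 when a peak had to cover at least 50% of a region.

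Regions marked in 1 line alone numbered 7631 in BxPC3, 3415 in Panc327 and 7662 in SUIT2. They made up 26.0% of the regions marked in BxPC3, 17.2% in Panc327 and 28.5% in SUIT2. The 12 pairs of libraries from different lines held between 6 and 325 regions of their own, with a median of 39. Such a region must be absent from the other library of both lines, so these counts are small by construction and set no baseline for the line-only counts. Regions missing from 1 line and marked in both others numbered 692 for BxPC3, 2468 for Panc327 and 2252 for SUIT2. The number for Panc327 rested on the agreement of its libraries: without Panc327 replicate 1 there were 7126 Panc327-only regions, and without replicate 2 there were 7616. The BxPC3-only count was 4661 with the same number of peaks from each list and 11740 without BxPC3 replicate 1. SUIT2-missing regions numbered 3962 without Panc327 replicate 1, and BxPC3-missing regions 1057 without Panc327 replicate 2. Counts after leaving out a library rise in part by construction, since a line with 1 library left needs only that library to mark a region.

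**Figure D2:**
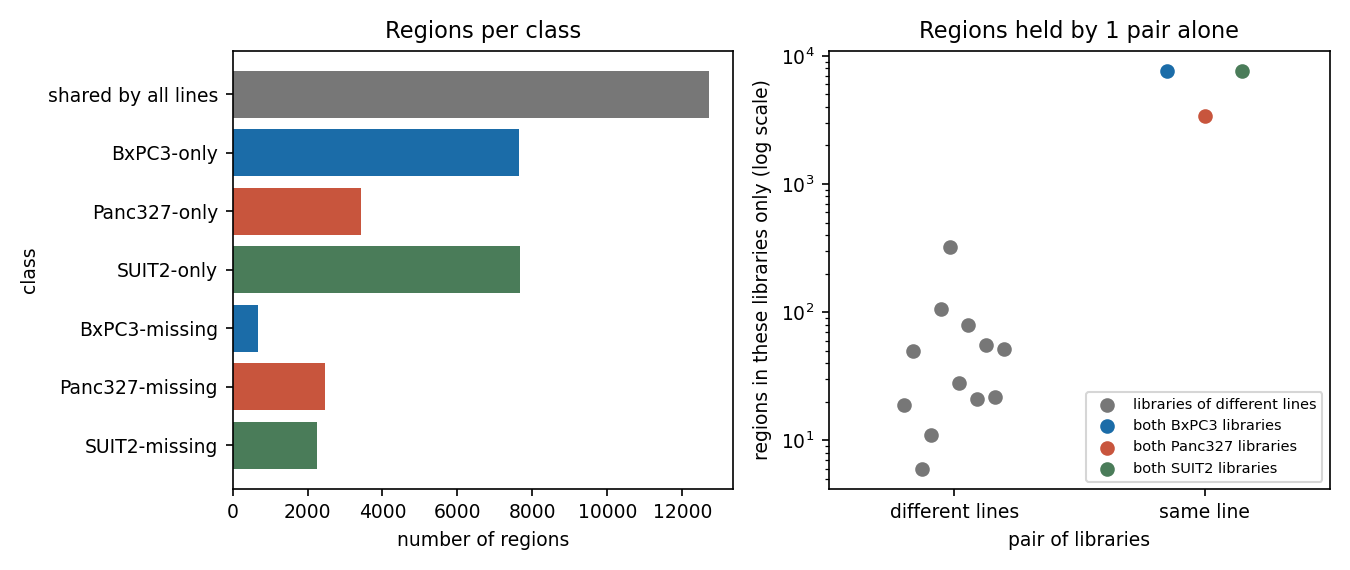
Left, number of merged regions (horizontal axis) per class; right, number of regions found in exactly 1 pair of libraries (log axis), for the 12 pairs from different lines and the 3 pairs from the same line. The pairs of the same line held 3415 to 7662 such regions and those of different lines 6 to 325, numbers kept small by construction.

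The broadest BxPC3-only region lay on chromosome 8, 32160494 to 32170577, with a highest fold over background of 44.7 in replicate 1 and 39.9 in replicate 2, the authors' own per-peak values. It lay in a 2 Mb window, 32 to 34 Mb, where the SUIT2 input background was 3.90 and 3.40 times the genome-wide level in replicates 1 and 2. Other broad BxPC3-only regions were on chromosome 22 at 46137916 to 46145723 (7808 bp), on chromosome 12 at 76113239 to 76120365 (7127 bp), on chromosome 14 at 37441314 to 37448431 (7118 bp) and on chromosome 6 at 143653425 to 143660391 (6967 bp). The 1 Mb window of chromosome 14 from 37000001 to 38000000 held 30 BxPC3-only regions among its 34 regions marked in BxPC3, the most of any such window in that line. The next windows of BxPC3 held 20 each, on chromosome 1 from 152000001, chromosome 8 from 32000001 and chromosome 20 from 22000001.

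In Panc327 the broadest line-only region was on chromosome 6, 44626794 to 44637487 (10694 bp). It was followed by chromosome 16, 1480431 to 1489716 (9286 bp), chromosome 5, 167369705 to 167378469 (8765 bp), and chromosome 5, 1882274 to 1889775 (7502 bp). A Panc327-only region on chromosome 20, 21490207 to 21496593, had a peak fold of 174.9 in replicate 1 and 36.1 in replicate 2, at percentiles 96.9 and 98.0 of those lists by −log10 q. It ranked 6 by width among the Panc327-only regions and was picked after the values were seen. The window of chromosome 19 from 39000001 to 40000000 held the most Panc327-only regions, 27 of the 67 marked in that line, and it lay inside a stretch where the Panc327 input background was raised (4.37 and 4.70 times the genome-wide level in replicates 1 and 2).

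**Figure D3:**
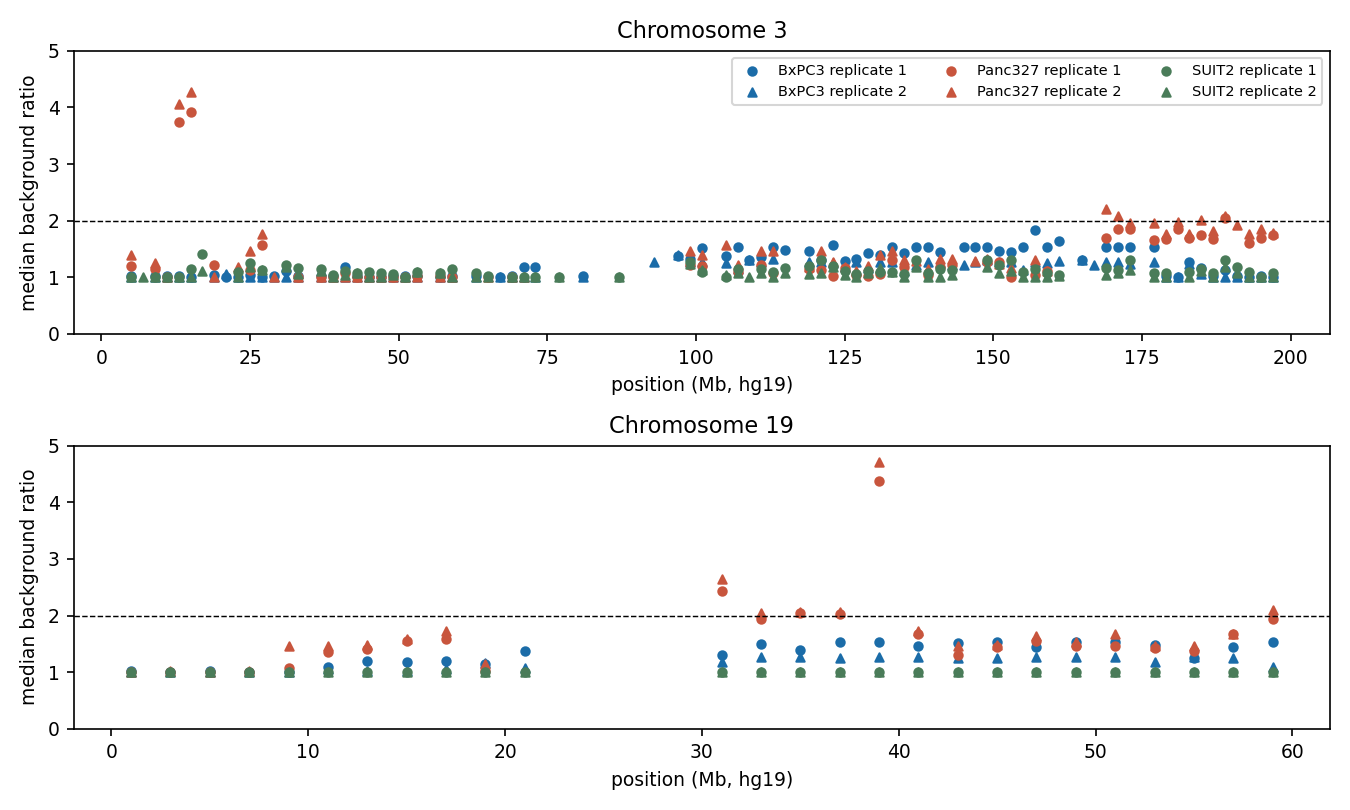
Median ratio of the input background behind the peaks to the genome-wide level, per 2 Mb window with at least 8 peaks, along chromosomes 3 and 19 (hg19, Mb), for the 6 libraries; the dashed line marks 2 times. Panc327 replicates 1 and 2 reached 4.37 and 4.70 on chromosome 19 from 38 to 40 Mb and 3.91 and 4.27 on chromosome 3 from 14 to 16 Mb, where no library of the other lines passed 1.53.

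SUIT2-only regions included the broadest of any line. The region on chromosome 3, 139006191 to 139033757, spanned 27567 bp with a highest fold of 65.6 in replicate 1 and 90.2 in replicate 2. It was followed by chromosome 5, 82844768 to 82866674 (21907 bp), chromosome 10, 32477621 to 32496974 (19354 bp), chromosome 16, 82058796 to 82077116 (18321 bp), and chromosome 10, 30981838 to 30997239 (15402 bp). All 10 of the broadest SUIT2-only regions were at least 13850 bp wide, wider than every BxPC3-only and Panc327-only region. The 1 Mb window with the most SUIT2-only regions was on chromosome 10 from 114000001, with 32 of 46 marked in SUIT2, followed by chromosome 7 from 117000001, with 26 of 30.

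Line-only H3K27ac was spread unevenly over the chromosomes. All classes are shares of the same marked regions, so an excess of any class on a chromosome leaves less room for the others. Regions shared by all lines were not tested, but chromosome 19 held 7.36% of them. It held 1.60% of BxPC3-only, 9.58% of Panc327-only and 2.01% of SUIT2-only regions. A low share of line-only regions there is therefore not by itself a trait of a line. BxPC3-only regions were rarer than expected on chromosomes 16, 17, 19 and 22 and more frequent on 4, 5, 8, 13 and 14. On chromosome 19, 122 were found against 364 expected from its share of marked regions (0.335 times, permutation adjusted p = 0.00115), and on chromosome 8, 469 against 330 (1.42 times, permutation adjusted p = 0.00115). Panc327-only regions showed the opposite tilt, above expectation on 16, 17, 19 and 22 and below it on 4, 8, 9 and X: chromosome 19 held 327 against 163 (2.01 times) and chromosome 17 held 309 against 171, both with permutation adjusted p = 0.00115. SUIT2-only regions were above expectation on 2, 4 and 10 and below on 14 and 19, with 154 against 365 on chromosome 19 (0.422 times, permutation adjusted p = 0.00115). Under the 9 alternatives run for the chromosomes, the calls on 8, 14, 17, 19 and 22 in BxPC3, on 8, 17, 19, 22 and X in Panc327 and on 2, 4, 10 and 19 in SUIT2 always passed. The others were lost in 1 or more: in BxPC3 chromosome 5 in 5, 4 in 2, and 13 and 16 in 1 each; in Panc327 chromosome 9 in 3, 16 in 2 and 4 in 1; in SUIT2 chromosome 14 in 3. Without Panc327 replicate 1, chromosome 16 of Panc327 had a permutation adjusted p of 0.476. Across the alternatives, the excess of Panc327-only regions went as low as 1.38 times on chromosome 19, 1.41 on 17 and 1.32 on 22. The permutation test shuffled blocks of 25 neighbouring regions 10000 times, two-sided, with Benjamini-Hochberg adjustment over 138 tests, and the smallest unadjusted p it can give is 0.0001. The test compares these libraries, and Panc327 entered it with libraries that themselves differed: chromosome 19 held 9.55% of the regions called in Panc327 replicate 1 alone and 3.14% of those called in replicate 2 alone.

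Regions missing from a line mirrored that pattern in part, and these classes too are shares of the same marked regions. BxPC3-missing regions were above expectation on chromosomes 17, 19, 21 and 22, with 24 against 8.19 on chromosome 21 (2.93 times, adjusted p = 0.00184) and 74 against 34.7 on chromosome 17 (2.13 times, adjusted p = 0.00115) in the same permutation test. Panc327-missing regions were above expectation on 4 and 13 and below on 16, 17 and 19. SUIT2-missing regions were above expectation on 1, 16 and 19 and below on 4, 6 and X. Of these calls, 17, 21 and 22 in BxPC3, 13, 17 and 19 in Panc327 and 1 in SUIT2 passed under all 9 alternatives. Panc327-missing regions lost chromosome 4 in 6 of them and 16 in 3, BxPC3-missing regions lost 19 in 2, and SUIT2-missing regions lost 16 in 3, 6 and X in 2 each, and 4 and 19 in 1 each. Without Panc327 replicate 1, SUIT2-missing regions stood at 0.986 times on chromosome 6, 1.06 on 16 and 0.755 on X (permutation adjusted p = 0.907, 0.713 and 0.195). The chromosome 19 excess of SUIT2-missing regions, 1.61 times with both Panc327 libraries, was 1.07 times without Panc327 replicate 1 (permutation adjusted p = 0.633), and that of BxPC3-missing regions went from 1.61 to 1.23 times (permutation adjusted p = 0.353).

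**Figure D4:**
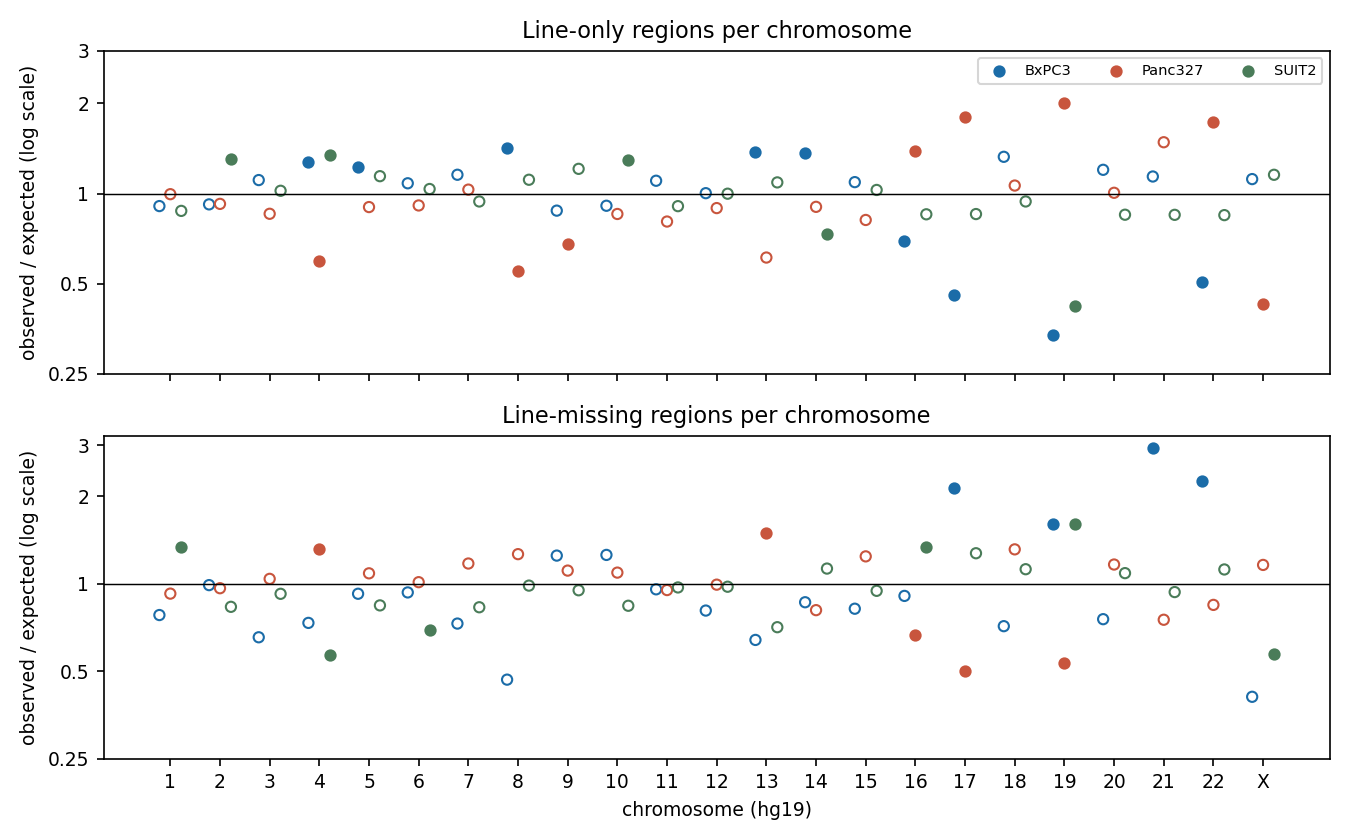
Observed over expected number of line-only (top) and line-missing (bottom) regions on a log axis, per chromosome, for BxPC3 (blue), Panc327 (red) and SUIT2 (green). Filled points passed the adjusted permutation test; on chromosome 19 Panc327-only regions stood at 2.01 times and BxPC3-only regions at 0.335 times the expectation.

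Some stretches held called peaks in both other lines and none in the line itself. Panc327 had 6 stretches with at least 10 regions that both other lines marked and with no peak of either of its libraries between them. BxPC3 and SUIT2 had 0. Regions not marked in both other lines could lie in between and were not counted. These numbers depended on single libraries: without Panc327 replicate 1 there were 7 stretches in SUIT2, 6 in Panc327 and 1 in BxPC3. BxPC3 had 2 without Panc327 replicate 2 and 2 without SUIT2 replicate 1, and SUIT2 had 1 without Panc327 replicate 2. A line with 1 library left needs only that library to mark a region, which by construction favours more stretches in the other lines. The Panc327 stretches were on chromosome X from 13000661 to 13508298 (12 regions), chromosome 5 from 58330503 to 59096126, chromosome 7 from 46017031 to 47013146, chromosome 8 from 29316096 to 29598082 and from 122156760 to 123583016 (11 regions each), and chromosome 4 from 10657198 to 11704089 (10 regions). With at least 5 regions, there were 29 stretches in Panc327, 13 in SUIT2 and 4 in BxPC3. Panc327 also had the fewest peaks and only 2 such stretches at a −log10 q of at least 20, a threshold chosen after the data were seen, and no test was made.

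A wider definition of a gap, chosen after the data were seen, took at least 20 regions with a peak in 2 or more of the other 4 libraries and none of the line between them. Panc327 had 30 such gaps with a total of 76.7 Mb, BxPC3 had 5 with 6.69 Mb and SUIT2 had 5 with 9.14 Mb. In BxPC3 the gap with the most regions ran on chromosome 9 from 20686150 to 23590715, where SUIT2 marked 29 regions and Panc327 6. BxPC3 and Panc327 both lacked peaks on chromosome 7 from 116595648 to 117510358, where SUIT2 marked 25 regions. In SUIT2 the gap with the most regions ran on chromosome 14 from 36790398 to 37640832, where BxPC3 marked 28 regions and Panc327 3. A peak list cannot tell a stretch that is absent from the DNA, one that is present without H3K27ac, and one with too little signal to be called.

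**Figure D5:**
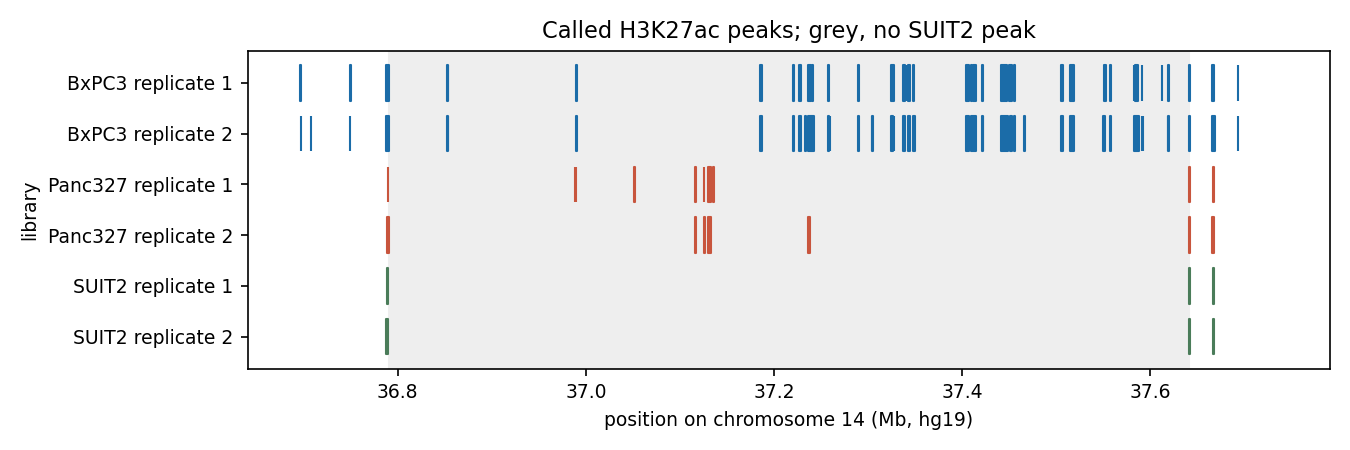
Called H3K27ac peaks (bars, drawn with a minimum width so that narrow ones stay visible) in the 6 libraries along chromosome 14 (hg19, Mb), with the interval 36790398 to 37640832 in grey. BxPC3 replicates 1 and 2 had 34 and 40 peaks there, Panc327 7 and 5, and SUIT2 0 and 0.

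Joining peaks called in both libraries of a line over gaps of up to 10 kb gave 20640 clusters in BxPC3, 15095 in Panc327 and 18910 in SUIT2. The largest SUIT2 cluster lay on chromosome 17 from 57822766 to 57943348 and covered 108187 bp, where BxPC3 covered 36277 bp and Panc327 9711 bp. Further large SUIT2 clusters were on chromosome 15 from 67339941 to 67489858 (104845 bp) and chromosome 7 from 130516794 to 130647733 (101750 bp). The largest BxPC3 cluster, on chromosome 1 from 209527778 to 209609198, covered 50525 bp, where SUIT2 covered 0 bp and Panc327 12887 bp. The largest Panc327 cluster was shared: chromosome 10 from 74002984 to 74092764 covered 32391 bp in Panc327, 28116 bp in BxPC3 and 30318 bp in SUIT2. A cluster on chromosome 19 ranked second in both BxPC3 (39126795 to 39201609) and Panc327 (39125439 to 39190778), and lay where the Panc327 input background was raised. Regions near transcript starts were not excluded from the clusters, and clusters were ranked only within a line.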

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

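The tests of the input background as a mapping effect and as chance were chosen only after the result was seen, as was the background measure itself; the test of line-only regions inside the windows was written before its result.

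The input background behind the peaks, which the caller set each pile-up against, was raised to at least 2 times the genome-wide level in both libraries of a line in 22 of 847 windows of 2 Mb in Panc327, 2 of 1034 in SUIT2 and 0 of 1105 in BxPC3. These values stood out as a signal in data outside the main measurement. In Panc327 the lower of the 2 library ratios peaked at 4.37 on chromosome 19 from 34 to 40 Mb, 3.91 on chromosome 3 from 12 to 16 Mb, 2.49 on chromosome 2 from 44 to 48 Mb, 2.43 on chromosome 19 from 30 to 32 Mb and 2.38 on chromosome 17 from 16 to 18 Mb. Further Panc327 windows reached 2.25 on chromosome 12 from 26 to 30 Mb, 2.23 on chromosome 18 from 8 to 12 Mb, 2.14 on chromosome 7 from 16 to 18 Mb, 2.11 on chromosome 18 from 2 to 4 Mb and 2.06 on chromosome 2 from 32 to 34 Mb. Others were 2.05 on chromosome 2 from 36 to 40 Mb, 2.04 on chromosome 3 from 188 to 190 Mb, 2.04 on chromosome 7 from 20 to 24 Mb and 2.02 on chromosome 12 from 32 to 34 Mb. In SUIT2 the ratio was 3.40 on chromosome 8 from 32 to 34 Mb, a window with only 8 and 9 peaks, and 2.13 on chromosome 12 from 58 to 60 Mb.

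Reads piling up at the same positions of hg19 in any human cell are argued against, since the highest ratio among the libraries of the other lines had a median of 1.29 over the 24 windows and was at most 1.70. Chance in 1 input library is argued against for Panc327 and SUIT2, where 28 of 29 windows raised in replicate 1 also passed the somewhat lower bound set for replicate 2 (96.6%, 95% Wilson interval 82.8 to 99.4). In BxPC3, 0 of 12 such windows did (0%, upper bound 24.2%). The bound was harder to reach there, since BxPC3 replicate 2 had a lower median ratio than replicate 1 on every chromosome. Chromosome 20 had the highest median of any chromosome in both BxPC3 libraries, at 1.90 and 1.64 in replicates 1 and 2. The test therefore cannot decide on chance for the BxPC3 windows. A candidate explanation that remains is extra copies of these windows in the DNA of Panc327, counted in part as H3K27ac of that line: 28.5% of the regions marked in Panc327 were Panc327-only inside the windows and 16.8% outside, a difference of 11.7 percentage points (95% interval 4.68 to 17.8, from redrawing windows). This contrast was not matched by chromosome, and some of the windows lay on chromosomes 17 and 19. With the windows of raised background taken out, Panc327-only regions still stood at 1.87 times the expectation on chromosome 17 and 1.90 times on 19. The contrast therefore cannot be told apart from the tilt over chromosomes. The windows held 169 of the 3415 Panc327-only regions, so most of that class lay outside them. Rises under 2 times were not taken out. In Panc327 replicates 1 and 2 the median background ratio was 1.42 and 1.54 on chromosome 19 and 1.44 and 1.53 on 17. On chromosome 20 it was 1.43 and 1.52, where Panc327-only regions stood at 1.01 times the expectation. What such rises add to the class was not tested.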

How the results depend on the processing

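The stricter −log10 q of at least 20, the removal of windows with raised background, leaving out libraries for stretches and clusters, and all chromosome results were chosen after seeing the data. The excess of overlap within lines was 0.364, 0.364 at a −log10 q of at least 20, 0.366 with the same number of peaks per list and 0.342 as the share of peaks overlapping by 50% of both. With the replicate number as a block, run for this overlap alone, it was 0.363. The replicate numbers paired no libraries. Counts of peaks, stitched clusters and most region classes stayed within 1.5 times under each alternative run. The exceptions were BxPC3-only regions with the same number of peaks per list (4661), and regions shared by all lines (5255) and SUIT2-missing regions (987) when a peak had to cover 50% of a region. Leaving out each library gave 7714 to 11740 BxPC3-only, 3451 to 7616 Panc327-only, 723 to 1057 BxPC3-missing and 2311 to 3962 SUIT2-missing regions. With 1 library left, a line needs only that library to mark a region. By construction this favours larger classes of its own and more missing regions and stretches in the other lines. Stretches numbered 4 in BxPC3, 29 in Panc327 and 13 in SUIT2 with at least 5 regions, and 2 in Panc327 at a −log10 q of at least 20. Leaving out each library gave 0 to 2 stretches in BxPC3 and 0 to 7 in SUIT2, rises that the same rule favours. How far it accounts for them was not tested. Of the 37 chromosome results, 21 passed under all 9 alternatives. All kept their direction under the alternatives run for them (the merging distance and the larger overlap were not), but 11 no longer passed at a −log10 q of at least 20, 11 without Panc327 replicate 1 and 7 with the same number of peaks per list. The planned −log10 q of at least 5 removed 0 peaks and was not run, and the planned promoter and gene list alternatives were not run without gene positions on hg19. Estimated depth was lowest in Panc327 replicate 1, at 13800000 tags; how many weak regions each library lost by depth was not measured.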

Other observations

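The tests of carried-over BxPC3 material and of dense chromosomes were chosen only after the result was seen; those of read depth and of raised windows were written before their results.

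Regions called in 1 library alone numbered 3538 and 3537 in Panc327 replicates 1 and 2, 712 and 3761 in BxPC3, and 977 and 2420 in SUIT2. In BxPC3 and SUIT2 the library with more estimated tags held more of them, and in Panc327 the numbers were nearly equal although replicate 2 had 24400000 estimated tags and replicate 1 13800000. The median fold of a peak was 23.2 in Panc327 replicate 1 and 11.1 in replicate 2, each the authors' value within its own list.

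Panc327 replicate 2 shared more regions with BxPC3 than Panc327 replicate 1 did, 1695 against 348 among regions that SUIT2 lacked. BxPC3 chromatin or reads carried into that library would add to each region in proportion to its BxPC3 pile-up, and the strongest BxPC3 regions left uncalled limit how much was carried. Of the strongest 10% not called in replicate 1, 33.7% were called in replicate 2 (95% Wilson interval 30.7 to 36.8), which allows at most 0.231 reads per read of pile-up in BxPC3 replicate 1 if the carried reads are Poisson. With that amount taken away, 61.5% of the 1695 regions would still be called (95% interval 59.1 to 63.8), which argues against carry-over as the whole cause. These 1042 regions are not matched for depth to the 348 of replicate 1, which had fewer estimated tags. A smaller carried share stays open, since the share called rose with the BxPC3 pile-up, from 12.1% in the weakest 10%. Fewer reads in replicate 1 are argued against as the whole cause: at the same pile-up in replicate 2, BxPC3-held regions were called in replicate 1 less often than SUIT2-held ones, by -15.1 percentage points (95% interval -18.4 to -12.0). A difference in the state of the cells may remain, but the labels give nothing that separates these libraries, and no biological explanation was tested.

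Regions called in 1 Panc327 library alone lay on different chromosomes in replicate 1 and replicate 2, with 9.55% and 3.14% on chromosome 19. The windows of raised background did not hold this difference, since without them the share on chromosome 19 was still 3.46 times as high in replicate 1 (95% interval 2.42 to 5.26). Those windows were by definition raised in both Panc327 libraries. The test therefore cannot decide on background raised in 1 library alone or by less than 2 times. A preference of 1 library for chromosomes dense in H3K27ac regions stays open: across 23 chromosomes, the log2 ratio of the shares rose with the regions of BxPC3 or SUIT2 per Mb (Spearman's rho = 0.505, permutation p = 0.0152, adjusted p = 0.0456; Pearson's r = 0.588, permutation p = 0.00303, adjusted p = 0.00909, over 3 lines). Without chromosomes 19 and 17, rho was 0.356 and r 0.30, so the relation rests on those chromosomes and may be no general trend. The same relation had rho = 0.269 in BxPC3 and -0.291 in SUIT2 (permutation p = 0.214 and 0.181). Without chromosomes 19 and 17 these were 0.361 (r = 0.450) in BxPC3 and -0.481 (r = -0.483) in SUIT2, no smaller in size than in Panc327, so the relation may not be particular to Panc327.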
